A study of Bos taurus with 6 samples.

How the data were processed

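The 6 arrays are 2-colour bovine oligonucleotide arrays hybridised with amplified antisense RNA of day 7 in-vitro blastocysts and of granulosa cells, labelled chemically with Cy3 and Cy5, per the labels' protocols. The labels describe 3 biological replicates with the dyes exchanged. How many animals each pool holds is not given in the sources used here. The p-values of probes and genes in the main test measure the spread between these 3 pools, which may be partly technical. The intensity columns used were the mean raw intensity of each spot and its median local background at 532 nm (Cy3) and 635 nm (Cy5), neither corrected nor normalized, per the file headers. The deposited files also hold a net intensity per channel. Per its values, the channel listed ahead in a file is raw minus background, and the other is rescaled to it along a curve that the sources used here do not describe. The scanner and its software are not given in the sources used here. The authors' value table, a score with no unit given, is the quotient of the log2 net intensities of the channels (100% of values within 1e-04), with a minus sign on the arrays titled blastocyst. It is not a log ratio. Its column medians are -0.998, -0.998 and -1.00 for blastocyst arrays 1 to 3 and 1.00, 0.999 and 1.00 for granulosa arrays 1 to 3, and after this match neither its scale, centring nor direction stays unknown. The file of granulosa array 2 lists 635 nm ahead of 532 nm, the reverse of the other 5, and all columns were read by wavelength name. The value table divides by position, so its numerator is Cy3 on that array and Cy5 on the others. Its column correlates at -0.82 and -0.72 with those of granulosa arrays 1 and 3 across probes, which correlate at 0.81 with each other.

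Analyses used R 4.3.3 and limma 3.58.1, and figures used Python 3.11.15 with matplotlib 3.10.9. Raw intensities were background-corrected with normexp and an offset of 50, fitted on all spots, and normalized within each array by loess with control spots at weight 0. Each ratio was turned to read blastocyst over granulosa. Of the spots on an array, 8 without a probe name were left out, and repeated spots of a probe were averaged. A probe was tested where it exceeded the 95th percentile of the 153 negative control spots on at least 3 of 6 arrays in the channel of at least one cell type. This left 35034 of 43794 probes (80.0%). The same-numbered arrays of opposite dye were then averaged, and the mean of the 3 replicates was tested against 0 with lmFit and eBayes on 3.35 degrees of freedom in all. A probe passed at a Benjamini-Hochberg adjusted p under 0.05 and an absolute log2 ratio of at least 1. Every adjusted p in the text comes from limma.

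Whether the numbers pair the arrays was checked on deviations from the mean of each orientation. These correlated across probes at 0.84 to 0.93 for same-numbered arrays and at -0.59 to -0.20 for arrays of different number and opposite dye, so the numbers were taken as pairing. The pairing comes from the titles. Fits on the 6 arrays with the replicate number as a block, with and without a dye term, were alternatives.

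The probe table given for the array pairs 21790 probes with 1 gene symbol and none with several, and 22004 probes are unnamed here. Symbols were updated through the RefSeq gene table of the ARS-UCD2.0 assembly. Of the named probes, 20068 had a current symbol, 1644 were updated through a synonym and 78 found no match and kept the older symbol. No coordinates are given, since the files name no genome build. For a gene with several probes the one with the highest mean log2 intensity over both channels was used. This applied to 3256 genes, and in 43 of them another called probe had the opposite sign. In 42 genes that passed, the brighter side was over 30000 on all 6 arrays. That ceiling was set after the pile-up of intensities near the scanner's upper limit had been seen, and such ratios may be understated. Where a gene was above background on no array of a cell type, the fold is given as a lower bound. The dim side was set per array to the higher of its own signal and the lowest signal counted as above background. For the genes named, such folds equal the measured fold, as for MEST, or lie little under it. These bounds rest on channel intensities after loess and Aquantile.

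Genes to name were chosen by a rule written before the data were examined, as were the tests, the gene lists and most of the alternatives. It takes the 12 largest log2 ratios in each direction among genes that passed with the same sign on all 6 arrays and above background in both cell types on at least 3 arrays each. It adds the 6 brightest genes above background in one cell type alone, up to 4 members of each list that passed and up to 2 that passed in the opposite direction. It always takes POU5F1, NANOG, SOX2, CDX2, GATA3, GATA6, KRT8, KRT18, CDH1, CYP19A1, FSHR, FOXL2, INHA, INHBA, FST, STAR, CYP11A1, ACTB and GAPDH. Genes without a symbol, numbered loci and probes of several genes were not named. FOXL2 did not pass the background filter, and GATA6 and GAPDH were not analysed here. The rule gave 116 genes, of which 106 passed.

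The 25 gene lists hold 835 genes, 27 of them on more than 1 list, and cover embryonic lineages, granulosa and other follicular cells, blood, metabolism, chromatin and stress. They were tested with camera at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over the lists. Of the 12 lists called, none held with an estimated correlation, where the adjusted p lay between 0.540 and 0.665. With 3 replicates that version had little power: cell cycle and immediate early genes, at a camera adjusted p of 2.52e-07 with the preset value, also came to 0.540. It therefore cannot tell which lists hold. With the preset value camera sets genes against genes, and its p does not measure the spread between the 3 replicates. With fry, which asks whether the genes of a list move on balance one way and does not compare it with other genes, 18 lists passed.

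The procedure was tested on simulated data of 43202 probes with the real spread between replicates and planted changes. At planted log2 ratios of 1, 1.5, 2 and 3 it recovered 52%, 66%, 94% and 96% of 50 probes each. Median estimates were 1.04, 1.51, 2.12 and 3.22, and 45 of 3209 calls were false. Probes called in the real arrays also entered as true changes, at their estimated ratio and with their own spread. Most of the 3209 calls were such probes, so the count of false calls is not an independent error rate. A planted list of 30 genes gave a camera p of 8.92e-23 and an unplanted one 0.522. Changes were planted only in probes brighter than the array medians, leaving out the brightest, so the recovery does not cover dim probes. Noise was drawn for each probe by itself. The false calls and the list p-values therefore do not cover genes that vary together, as lists did between these pools. Alternatives changed the background correction, the normalization, the filter, the handling of replicates, the thresholds, the probe standing for a gene and the set test, left out each replicate and each array, and used the authors' value table. For 6 values missing from that table the ratio was set to no difference. An alternative with the slide or scan as a block was not run, since no slide or scan was identified for the arrays here.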

Results

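RNA from bovine blastocysts was compared with RNA from bovine granulosa cells on 6 oligonucleotide arrays carrying 43794 named probes. Blastocysts are embryos of the stage at which an outer epithelium, the trophectoderm, encloses a fluid-filled cavity and the inner cell mass. They were produced in vitro and collected on day 7 after fertilisation with semen pooled from 3 bulls, starting from oocytes of follicles measuring 3 to 6 mm. Granulosa cells are the somatic cells that line the ovarian follicle and surround the oocyte. They were aspirated under ultrasound guidance from lactating Holstein cows given 6 doses of 40 mg follicle-stimulating hormone (FSH), 44 h after the last dose, then picked under a microscope and washed. Every array carried both RNAs, one in Cy3 and the other in Cy5. In 3 arrays the blastocyst RNA was in Cy3 and in 3 it was in Cy5, and the titles number the arrays 1 to 3 in each orientation. Same-numbered arrays were averaged, which left 3 replicates. Raw median intensities ran from 189 to 386 in Cy3 and from 177 to 210 in Cy5. Between 64.0% and 77.0% of probes lay above background in the blastocyst channel and between 58.2% and 78.3% in the granulosa channel. These shares followed the dye. Blastocyst RNA gave 72.1% to 77.0% in Cy3 and 64.0% to 69.2% in Cy5, and granulosa RNA 76.0% to 78.3% in Cy3 and 58.2% to 60.3% in Cy5. The number of arrays limits the precision of every value given here.

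The main question was which transcripts differ in abundance between the embryo and the follicular cells. ATP6V0D2, a subunit of the vacuolar proton pump, was 121-fold higher in blastocysts (log2 ratio 6.92 ± 0.13, SD, n = 3, adjusted p = 0.00204). Its partner subunit ATP6V0A4 was 80.1-fold higher (6.32 ± 0.42) by its brighter probe, while the other gave 0.37 and the mean of both 3.35. TFAP2C, a transcription factor of the trophectoderm, was 111-fold higher (6.80 ± 0.34), against 3.33 as the mean of its probes and 2.71 by the probe left without those near the scanner limit. Among the largest log2 ratios towards granulosa cells were those of SRGN, the core protein of a secretory granule proteoglycan (-7.42 ± 0.65, 171-fold), VIM, an intermediate filament protein of mesenchymal cells (-7.18 ± 1.18), and GJA1, the gap junction protein connexin 43 (-7.17 ± 0.37). Signals near the scanner limit, on all 6 arrays for VIM and on 2 for SRGN and GJA1, leave their order open. The other GJA1 probe gave -1.82, and the GJA1 call ended where probes near the scanner limit were left out (adjusted p = 0.0928). INHA, the alpha subunit of inhibin, stood at -6.69 ± 0.16 by a probe near the scanner limit on 4 of 6 arrays, which can hold down both its ratio and its SD.

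Of 35034 probes tested, 3553 (10.1%) passed limma's adjusted p of 0.05 with an absolute log2 ratio of at least 1, 1734 of them higher in blastocysts and 1819 higher in granulosa cells. With the brightest probe standing for each gene, 1773 of 13225 genes passed, 757 higher in blastocysts and 1016 in granulosa cells. Differences of at least 4-fold were found for 245 genes in blastocysts and 464 in granulosa cells, and differences of at least 64-fold for 5 and 19. Probes without a gene symbol here made up 1391 of the 3553. The calls depended on the replicates: 2191 probes and 1029 genes passed without replicate 1, and with limma none passed without replicate 2, where 8503 probes and 3889 genes had an unadjusted p under 0.05. Without replicate 3, 2541 probes and 1309 genes passed. All 106 named genes past the threshold lost their call without replicate 2, 48 without replicate 1 and 32 without replicate 3, although STAR alone among the 116 named genes changed sign in these fits.

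**Figure D1:**
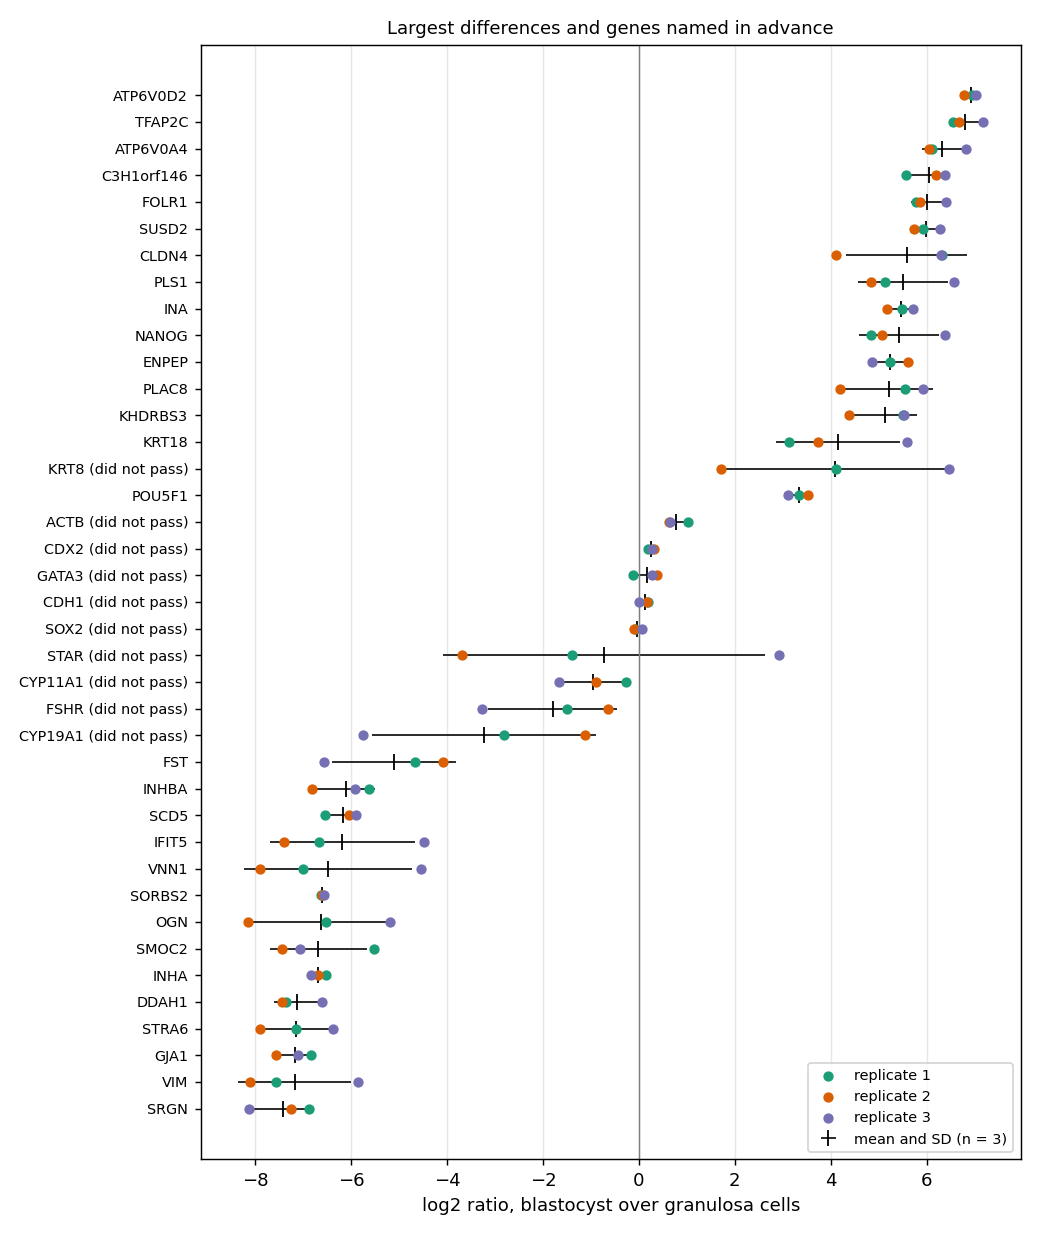
Log2 ratio of blastocyst over granulosa cells (horizontal axis) for the genes with the largest differences in each direction and the tested genes named in advance (vertical axis). Coloured points are the 3 replicates, each the mean of 2 dye-swapped arrays, and black marks with bars are the mean and SD; INHA lies at -6.69 with an SD of 0.16, whereas STAR spans -3.69 to 2.92.

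The other genes with the largest ratios towards blastocysts were C3H1orf146 (6.05 ± 0.43), FOLR1, a folate receptor (6.01 ± 0.34), SUSD2 (5.98 ± 0.28), CLDN4, a tight junction protein (5.58 ± 1.27), PLS1, an actin-bundling protein of microvilli (5.51 ± 0.93), INA (5.46 ± 0.28), ENPEP (5.23 ± 0.38), PLAC8 (5.22 ± 0.92) and KHDRBS3 (5.14 ± 0.66). Their adjusted p lay at or below 0.0186. Towards granulosa cells they were STRA6, a retinol transporter (-7.14 ± 0.76), DDAH1 (-7.14 ± 0.46), SMOC2 (-6.68 ± 1.02), OGN, a small proteoglycan of connective tissue (-6.62 ± 1.49), SORBS2 (-6.60 ± 0.04), VNN1 (-6.48 ± 1.74), IFIT5 (-6.18 ± 1.51) and SCD5, a fatty acid desaturase (-6.16 ± 0.35), with an adjusted p at or below 0.0248. TFAP2C and PLAC8 on the blastocyst side and VIM on the granulosa side were over 30000 intensity units on all 6 arrays, near the upper limit of the scanner. On the granulosa side STRA6 was so on 5 arrays, VNN1 on 4, SMOC2 on 3, DDAH1 on 2 and OGN on 1. Among the 106 named genes that passed, 41 had more than 1 tested probe, and in 32 of these another probe did not pass. The other probe gave 1.78 for C3H1orf146 and 2.20 for FOLR1, with means of 3.91 and 4.11 over both. TFAP2C ranged from 0.48 to 6.80 over its 3 probes, INA from -0.08 to 5.46 over 3, PLAC8 from -1.26 to 5.22 over 5, SORBS2 from -6.60 to -0.81 over 4 and STRA6 from -7.14 to -0.11 over 2. The call of STRA6 ended without probes near the limit, where the other probe stood for it, and that of SORBS2 (-0.89) where both cell types had to be above background on all arrays.

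In 15 genes that passed, signal lay above background on the blastocyst side and on no array on the granulosa side. The brightest were DPPA3, a maternal factor that protects DNA methylation (at least 46.0-fold higher), NANOG, a transcription factor of pluripotent cells (at least 40.1-fold), IFNT, the interferon by which the ruminant conceptus signals to the uterus (at least 31.4-fold), PLLP (at least 20.0-fold), POU5F1, the pluripotency factor OCT4 (at least 9.89-fold), and CT47B1 (at least 7.49-fold). The reverse held for 31 genes, of which the brightest were EMID1 (at least 23.0-fold), CARD6 (at least 21.0-fold), TOX (at least 18.5-fold), CDH12 (at least 14.3-fold), CADPS2 (at least 13.4-fold) and VEGFC, a growth factor of lymphatic vessels (at least 8.20-fold). These folds hold for the probe used and are not conservative bounds. For EMID1, CARD6, CDH12, CADPS2 and VEGFC the fold is the measured one, set by the dim side's own signal. For the others the lowest signal counted as above background held it slightly under the measured fold, at most from 35.5 to 31.4 for IFNT. For 3 of the genes other probes did not pass, giving 0.31 for DPPA3, 0.38 for PLLP, and -0.32 and -0.15 for CARD6. The means over all probes were 2.92, 2.36 and -1.62, and the CARD6 call also ended without background correction (adjusted p = 0.0514).

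Some lineage genes of the embryo were higher in blastocysts, while most of those tested did not pass. Of 17 tested pluripotency and inner cell mass genes, 5 were higher in blastocysts and none in granulosa cells, namely DPPA3, NANOG and POU5F1, with the lower bounds given above, SPIC (2.27 ± 0.46) and PRDM14 (1.33 ± 0.34), the last chosen after its values were seen. A further probe gave 0.30 for SPIC and 0.22 for PRDM14. SOX2 stood at -0.04 ± 0.09 (adjusted p = 0.679), with a dim log2 intensity of 7.19 in blastocysts and 7.23 in granulosa cells. DPPA3, above background on no granulosa array, read 6.88 there, so a probe this dim may be unable to show a difference. The list median was 0.49, with a camera adjusted p of 0.000335, against an adjusted p = 0.540 with an estimated correlation. Of 32 trophectoderm genes, 9 were higher in blastocysts, among them TFAP2C, PLAC8, IFNT (at least 31.4-fold) and the homeobox gene DLX4 (4.32 ± 0.16), and 2 were higher in granulosa cells, PPARG (-3.96 ± 1.04) and ID2 (-3.63 ± 0.95). Adjusted over the list alone, these counts were 11 and 2. The camera adjusted p was 0.00126, and the adjusted p = 0.540 with an estimated correlation. The keratin gene KRT18 passed (4.15 ± 1.29), whereas its partner KRT8 did not (4.10 ± 2.38, adjusted p = 0.0931) and gave 4.11, 1.71 and 6.47 in replicates 1 to 3. KRT8, near the scanner limit on all 6 arrays, passed on the 6 arrays with the replicate number as a block and a dye term (adjusted p = 0.0141). That fit used a common correlation for all probes and may understate the spread between replicates of a gene that varied this much. CDX2 (0.26 ± 0.06, adjusted p = 0.0625) and GATA3 (0.18 ± 0.27, adjusted p = 0.384) did not pass. The CDX2 probe was above background on 3 of 6 arrays in blastocysts, and GATA3 turned to -0.02 without normalization. Both were about as dim as SOX2, at 7.16 and 6.90 for CDX2 and 7.22 and 7.04 for GATA3 in blastocysts and granulosa cells. In the primitive endoderm list of 22, HDAC1 (1.47 ± 0.36) was higher in blastocysts and FST (-5.10 ± 1.29) and LAMA1 (-3.15 ± 0.70) in granulosa cells, with a camera adjusted p of 0.580.

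Of 42 genes of epithelial junctions and of ion and water transport into the blastocoel, the fluid cavity, 13 were higher in blastocysts and none in granulosa cells, and 17 adjusted over the list alone. CLDN4, the desmosome protein DSP (3.82 ± 0.75), CLDN6 (3.38 ± 0.57) and the splicing regulator ESRP1 (2.94 ± 0.76, other probes down to 0.12) led them. The list median was 0.44, the camera adjusted p 7.67e-07, and the adjusted p = 0.540 with an estimated correlation. CDH1 gave 0.12 ± 0.11 (adjusted p = 0.280) and -0.08 without normalization. EPCAM, an epithelial adhesion molecule chosen after its values were seen, had log2 ratios of 5.39, 0.36 and 7.74 in replicates 1 to 3 and did not pass (adjusted p = 0.168). In the granulosa RNA of replicate 2 its log2 intensity was 14.54, against 9.52 and 7.33 in replicates 1 and 3, and 11 of the 13 list members that differed between granulosa pools were brightest in pool 2. Here and below, such members had an adjusted p under 0.05 in limma's F test of the ratio over replicates. They also had a log2 range of at least 1 in the granulosa channel, which was not tested by itself.

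Some genes of cell division were higher in blastocysts. In the list of 54 cell cycle and DNA replication genes, 15 were higher in blastocysts, including RRM2, a subunit of ribonucleotide reductase (3.53 ± 1.12), the spindle checkpoint gene MAD2L1 (2.80 ± 0.46), cyclin CCNE1 (2.68 ± 0.16) and the checkpoint kinase CHEK1 (2.51 ± 0.71), and 22 adjusted over the list alone. The 4 probes of RRM2 went down to -0.04, and its call ended without probes near the scanner limit (1.58, adjusted p = 0.137). MCM2, a replication helicase subunit, was higher in granulosa cells (-2.50 ± 0.47), with other probes of that gene up to -0.06 and a mean of -0.98 over all 3, short of the ratio required. The camera adjusted p was 2.52e-07 for a median of 0.66, and the adjusted p = 0.540 with an estimated correlation. Of the 26 list members counted as differing between granulosa pools, 23 were brightest in pool 3.

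A few respiratory chain genes were higher in blastocysts. Of 40 oxidative phosphorylation genes, 6 were higher in blastocysts and none in granulosa cells, led by CYC1 (2.18 ± 0.46), ATP5MC1 (1.61 ± 0.24), COX8A (1.52 ± 0.43) and UQCRC2 (1.23 ± 0.16). The other CYC1 probe gave -0.05 and the mean of both 1.07, and ATP5MC1 was near the scanner limit on all 6 arrays. The count was 9 adjusted over the list alone, the median 0.41, the camera adjusted p 9.47e-05 and the adjusted p = 0.540 with an estimated correlation. Medians were 0.44, 0.60 and 0.25 in replicates 1 to 3, and all 8 members that differed between granulosa pools were brightest in pool 3. Glycolysis genes split. HK2 (3.05 ± 1.09), the lactate and pyruvate carrier SLC16A1 (3.04 ± 0.85) and 2 others of 19 were higher in blastocysts, whereas TPI1 (-3.86 ± 0.30), the lactate exporter SLC16A3 (-3.15 ± 0.38) and 3 others were higher in granulosa cells (camera adjusted p = 0.232). Other probes went down to 0.20 for HK2 and 1.03 for SLC16A1. In the list of 30 polyamine and amino acid transport genes, AMD1, which commits to polyamine synthesis (2.90 ± 0.36), SLC7A5 (2.80 ± 0.72), SLC15A1 (2.19 ± 0.28) and 2 others were higher in blastocysts and SLC38A2 in granulosa cells (-2.28 ± 0.34), with a camera adjusted p of 0.0848. SLC38A2 was near the scanner limit on all 6 arrays, and its direction turned to 0.09 without such probes.

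DNMT3A, a de novo DNA methyltransferase, was 18.7-fold higher in blastocysts (4.23 ± 0.18), with its blastocyst signal near the scanner limit on all 6 arrays. Its other probes went down to 1.04, the mean of all 3 gave 2.20, and without probes near the limit the value was 1.34. It belonged to 7 of 41 DNA methylation and chromatin genes higher in blastocysts, with DNMT3B (1.42 ± 0.33), SIRT1 (1.95 ± 0.66) and HDAC1 among the rest and none higher in granulosa cells (camera adjusted p = 0.0769). Adjusted over the list alone, 8 were higher in blastocysts and 1 in granulosa cells. Other SIRT1 probes went down to 0.36. Of 21 imprinted genes, which are expressed from one parental allele, 4 were higher in granulosa cells, SGCE (-2.97 ± 0.14), MEST (at least 5.27-fold), SNRPN (-1.06 ± 0.31) and GNAS (-1.02 ± 0.17), and none in blastocysts (camera adjusted p = 0.0839). SNRPN and GNAS, the latter near the scanner limit on all 6 arrays, lost their call with median centring (-0.99 and -0.75), and other probes gave up to 0.06 and 0.22. Of 19 oocyte and maternal effect genes, DPPA3 was higher in blastocysts and KPNA7, an importin (-2.00 ± 0.20), in granulosa cells (camera adjusted p = 0.233). Of 6 imprinted genes counted as differing between granulosa pools, 5 were brightest in pool 2. Other KPNA7 probes gave up to 0.05, and the mean of all 3 was -0.68.

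Some granulosa genes were higher in granulosa cells, and others varied between replicates and did not pass. Of 25 genes of granulosa identity and gonadotrophin response, 8 were higher in granulosa cells and none in blastocysts, and 11 adjusted over the list alone. GJA1 and INHA led with INHBA, the activin and inhibin beta A subunit (-6.11 ± 0.62, near the scanner limit on all 6 arrays), and FST, the activin-binding protein follistatin (-5.10 ± 1.29). The list median was -1.29, the camera adjusted p 0.000393, and the adjusted p = 0.540 with an estimated correlation. CYP19A1, the aromatase that makes oestradiol, gave -2.82, -1.13 and -5.74 in replicates 1 to 3 and did not pass (-3.23 ± 2.33, adjusted p = 0.134). The FSH receptor gene FSHR gave -1.49, -0.64 and -3.27 (-1.80 ± 1.34, adjusted p = 0.141). Both passed on the 6 arrays with the replicate number as a block and a dye term (adjusted p = 0.0217 for CYP19A1 and 0.0490 for FSHR). That fit used a common correlation of 0.66 for all probes. Both genes differed between replicates beyond the spread of same-numbered arrays (limma's F test, adjusted p = 1.10e-07 and 0.000434). The block fit may therefore overstate their precision. Medians of the list were -0.67, -1.13 and -1.84 in replicates 1 to 3, and 6 of the 8 members that differed between granulosa pools were brightest in pool 3.

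Steroid synthesis genes had no common direction. Of 31 genes of steroidogenesis and cholesterol supply, SOAT1 (1.90 ± 0.52) and EBP (1.25 ± 0.41) were higher in blastocysts and GSTA1 (-2.84 ± 0.59) and CYB5A (-2.03 ± 0.48) in granulosa cells (camera adjusted p = 0.973; the median was -0.06 where camera pointed up). CYB5A turned to 0.61 without probes near the scanner limit and gave -0.51 as the mean of its 3 probes, and the EBP call ended with the net intensities (adjusted p = 0.0506). STAR, which moves cholesterol into mitochondria, gave -1.39, -3.69 and 2.92 in replicates 1 to 3 (-0.72 ± 3.36, adjusted p = 0.753), and CYP11A1, which starts steroid synthesis there, -0.95 ± 0.70 (adjusted p = 0.141). Of 15 list members that differed between granulosa pools, 12 were brightest in pool 3. Without replicate 2 the STAR ratio turned to 0.77. Of 28 genes of the ovulatory and luteinising response, 4 were higher in granulosa cells and none in blastocysts, VNN1, EGR1 (-5.28 ± 0.36), NR4A1 (-4.92 ± 0.37) and the progesterone receptor PGR (-3.61 ± 0.80). The camera adjusted p was 0.0180 and the adjusted p = 0.609 with an estimated correlation. List medians were -1.03, -2.23 and -0.10 in replicates 1 to 3, beside -1.28, -1.53 and -0.03 for theca and stroma genes, and of 20 members that differed between granulosa pools 9, 9 and 2 were brightest in pools 1 to 3.

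Immediate early genes, which are transcribed within minutes of a stimulus, were the fixed list with the lowest mean ratio. Of 23 tested, 11 were higher in granulosa cells and none in blastocysts, and 14 adjusted over the list alone. FOS (-5.68 ± 0.25), BTG2 (-5.43 ± 0.23), EGR1 and NR4A1 were among them, and the list median was -2.16. FOS, BTG2 and NR4A1 were near the scanner limit on 5 of 6 granulosa arrays, which leaves their order open. A further FOS probe gave -0.03 and stood for the gene without probes near the scanner limit, where the call ended. The camera adjusted p was 2.52e-07 and the adjusted p = 0.540 with an estimated correlation. Medians were -2.40, -2.63 and -1.48 in replicates 1 to 3, beside -1.28, -1.53 and -0.03 for theca and stroma genes, and of 8 members that differed between granulosa pools 4, 4 and 0 were brightest in pools 1 to 3.

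**Figure D2:**
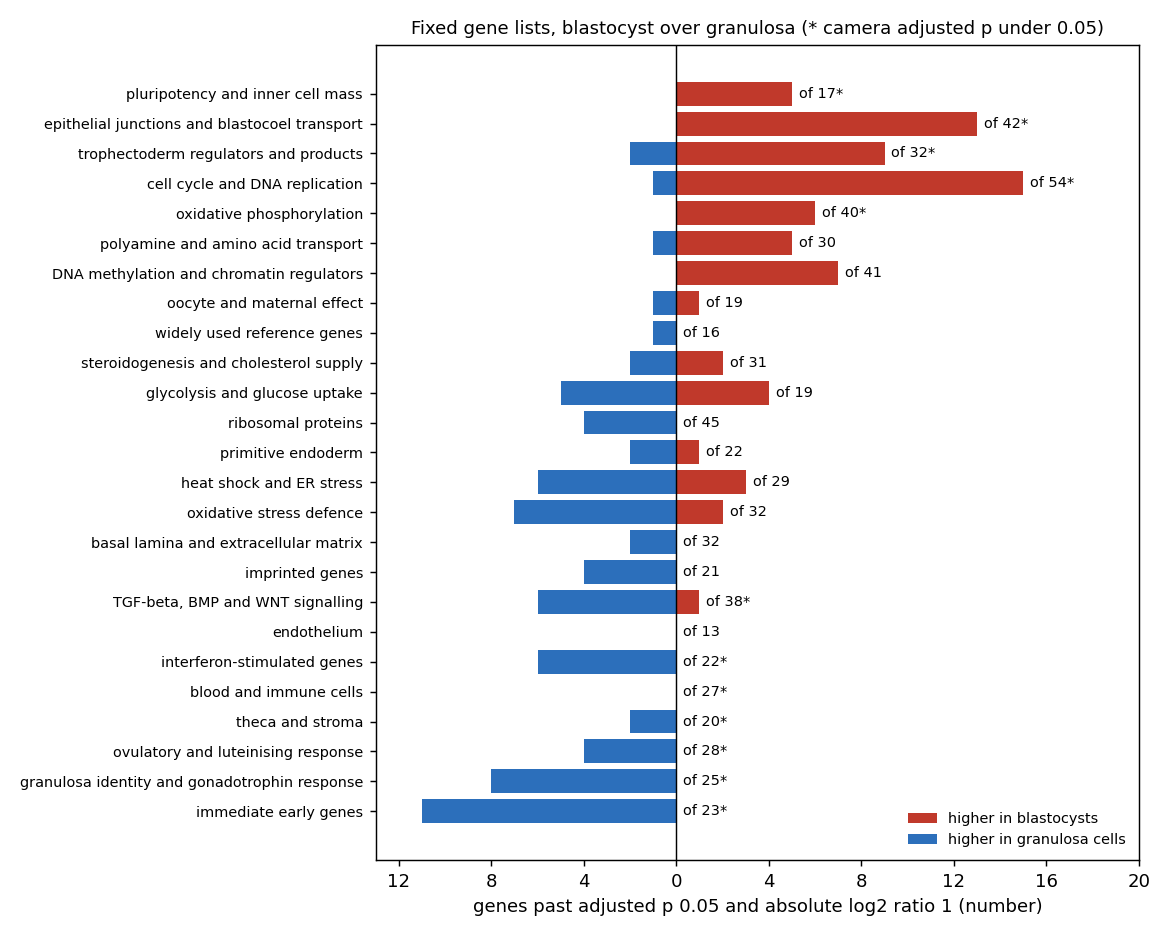
Number of genes past the threshold (horizontal axis) in each of the 25 fixed gene lists (vertical axis, ordered by mean log2 ratio), red for genes higher in blastocysts and blue for genes higher in granulosa cells, with the number tested beside each bar. Cell cycle genes have the most calls towards blastocysts (15 of 54) and immediate early genes the most towards granulosa cells (11 of 23). Asterisks mark a camera adjusted p under 0.05, and none holds with an estimated correlation, which had little power.

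Markers of other cells of the follicle and its wall were unequal between the replicates, and the single markers given intensities here were chosen after their values were seen. Of 20 theca and stroma genes, OGN and TCF21 (-1.91 ± 0.44) were higher in granulosa cells, and the camera adjusted p was 0.0435, against an adjusted p = 0.665 with an estimated correlation. The call ended without replicate 1 (adjusted p = 0.104) and without replicate 2 (adjusted p = 0.0962), with medians of -0.61 and -0.45, against -0.75 in all and -1.44 without replicate 3 (adjusted p = 0.00127). List medians were -1.28, -1.53 and -0.03 in replicates 1 to 3. COL3A1, a fibrillar collagen, had log2 intensities of 15.14, 15.19 and 10.41 in the granulosa RNA of replicates 1 to 3, and COL1A2, another, of 13.46, 14.33 and 7.57. Of 27 blood and immune cell genes none passed, with limma, 0 adjusted over the list alone, while the list as a whole lay lower than other genes (median -1.09, camera adjusted p = 0.00348, adjusted p = 0.665 with an estimated correlation). Its medians were -2.00, -0.90 and -0.19 in replicates 1 to 3, and -0.58 without replicate 1 and -1.71 without replicate 3. LYZ, lysozyme, had log2 intensities of 15.14, 9.32 and 9.53 in the granulosa RNA, and the haemoglobin gene HBB of 12.97, 8.85 and 8.95. None of 13 endothelial genes passed either (median -0.22, camera adjusted p = 0.210, and 0.00474 without replicate 3), and KDR, a receptor of blood vessel endothelium, stood at 12.16, 11.85 and 6.82.

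**Figure D3:**
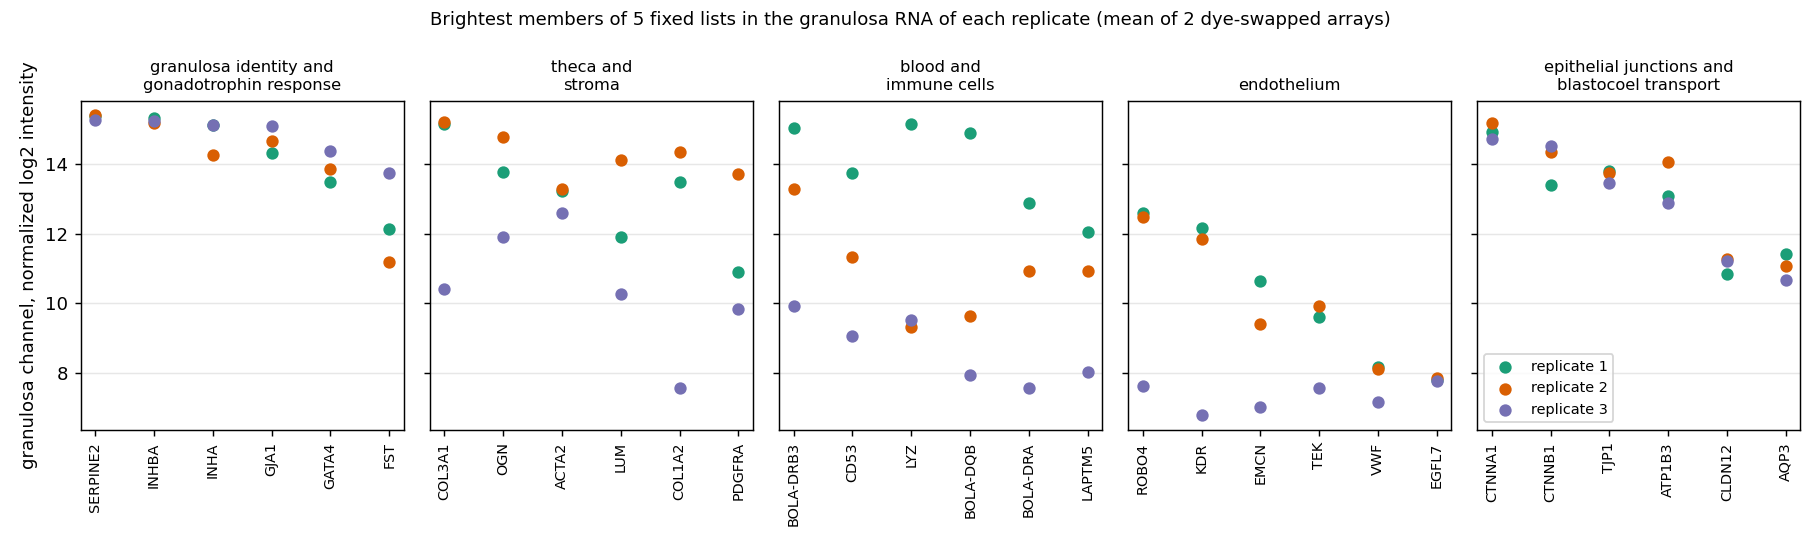
Normalized log2 intensity in the granulosa channel (vertical axis) of the 6 brightest members of each of 5 fixed lists (horizontal axis), 1 point per replicate, each the mean of 2 dye-swapped arrays. COL3A1 lies at 15.14, 15.19 and 10.41 and LYZ at 15.14, 9.32 and 9.53 in replicates 1 to 3. INHBA lies between 15.16 and 15.30 in all 3, but near the scanner limit on all 6 arrays, which can hide differences between pools. FST, on the same list, lies at 12.12, 11.18 and 13.74.

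Among stress and defence genes, the larger ratios pointed to granulosa cells. Of 29 heat shock and endoplasmic reticulum stress genes, HERPUD1 (-4.48 ± 0.51), BAG3 (-1.57 ± 0.61) and 4 others were higher in granulosa cells and ASNS (1.93 ± 0.34), HSPA9 (1.45 ± 0.40) and 1 other in blastocysts (camera adjusted p = 0.0839). Of 32 oxidative stress genes, GPX8 (-5.17 ± 0.43), TXNIP (-4.59 ± 0.94), GSTA1, SOD1 (-2.50 ± 0.51) and 3 others were higher in granulosa cells and the peroxiredoxin PRDX2 (1.74 ± 0.32) and GSTP1 (1.57 ± 0.58) in blastocysts (camera adjusted p = 0.0839). Without background correction the calls of BAG3 (adjusted p = 0.0621) and GSTP1 (adjusted p = 0.0522) ended, and other probes gave -0.80 for GPX8, -1.22 for TXNIP (mean of both -2.90) and down to 0.05 for GSTP1. Of 22 interferon-stimulated genes, 6 were higher in granulosa cells and none in blastocysts, among them IFI27 (-3.02 ± 1.09), IFIH1 (-2.57 ± 0.56), RSAD2 (at least 5.75-fold) and ISG15. Adjusted over the list alone, 6 were higher in granulosa cells and 1 in blastocysts. The camera call of the list ended in 4 of 29 alternatives. The ISG15 probe was above background on 1 of 6 blastocyst arrays, so the size of its ratio is not given, and its other probe gave -0.62. Another IFI27 probe gave 0.05. The camera adjusted p was 0.0180 and the adjusted p = 0.540 with an estimated correlation. List medians were -0.81, -0.33 and -0.06 in replicates 1 to 3, beside -2.00, -0.90 and -0.19 for blood and immune genes, and 4 of the 6 members that differed between granulosa pools were brightest in pool 1.

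Of 38 genes of TGF-beta, BMP and WNT signalling, 6 were higher in granulosa cells, with ID3 (-4.26 ± 0.68), ID2, the BMP receptor BMPR1B (-3.38 ± 0.05) and SMAD2 (-2.56 ± 0.75) at their head, and SMAD1 was higher in blastocysts (1.67 ± 0.53). Other probes gave up to -0.16 for ID3 and -0.22 for BMPR1B, whose call ended where both cell types had to be above background on all arrays (-0.66). The camera adjusted p was 0.0449 and the adjusted p = 0.644 with an estimated correlation. The call of the list ended in 10 of 29 alternatives, and its median ran from -0.46 to -0.10 outside the value table. List medians were -0.13, -0.58 and -0.06 in replicates 1 to 3. Of 32 basal lamina and extracellular matrix genes, LAMA1 and TIMP2 (-1.01 ± 0.09) were higher in granulosa cells (camera adjusted p = 0.210). Medians of that list were -0.37, -0.75 and 0.01, beside -1.28, -1.53 and -0.03 for theca and stroma genes, and 13 of the 17 members that differed between granulosa pools were brightest in pool 2. Of 45 ribosomal protein genes, RPS14 (-2.37 ± 0.57), RPL18 (-1.46 ± 0.20), RPS19 (-1.05 ± 0.33) and RPL15 (-1.02 ± 0.18) were higher in granulosa cells, and the median of -0.16 turned to 0.06 with median centring in place of loess (camera adjusted p = 0.0503). TIMP2 (-0.83), RPS19 (-0.95) and RPL15 (-0.76) lost their call with median centring. RPL15 was near the scanner limit on all 6 arrays and turned to 0.03 without such probes. Among 16 widely used reference genes, CHUK (-1.69 ± 0.18) was higher in granulosa cells (camera adjusted p = 0.894), and ACTB differed by 0.77 ± 0.22, under the ratio required (adjusted p = 0.0311).

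Dye effects were present, and same-numbered arrays lay closer to each other than to the rest. On the 6 arrays, 5883 probes had a dye effect past limma's adjusted p of 0.05. None had without each replicate in turn, where 7231 to 9602 had an unadjusted p under 0.05. This fit left out the pairing of same-numbered arrays, so the spread between replicates entered its error and the counts may be too low. Same-numbered arrays of opposite dye correlated across probes at 0.90 to 0.91, and arrays of different number and opposite dye at 0.71 to 0.79. The replicate means correlated at 0.79 to 0.86. These are correlations across probes, which are not independent replicates.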

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

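The tests on the value table in this part were chosen after the result was seen; the count over other splits of the arrays was planned. A signal in data outside the main measurement drew attention to control spots. The 320 E1A spike-in spots had a median log2 intensity 5.79 above the negative control spots in Cy5 and 4.42 in Cy3, and the 36 DCP control spots 5.26 and 3.89. These controls entered no comparison of the cell types.

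The deposited value of granulosa array 2 runs against those of granulosa arrays 1 and 3, with correlations of -0.82 and -0.72 across probes. Exchanged wavelength names in its scanner output are argued against: read by the file's own header, the spike-in log2 ratio of Cy5 over Cy3 on that array correlated at 0.970 with the mean of the other 5. A quotient taken by column position has what it needs, since 100% of the values equal the quotient of the later over the earlier net intensity column, and that file lists its wavelengths in the other order. No biological explanation was tested.

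With 3 arrays against 3 there are 10 splits, too few for a share under 0.05. Fitted on the 6 arrays, 1 of the 10, the real one, gave as many as 4941 probes, and the highest of the others gave 22. Of the others, the 3 that like the real one part all 3 same-numbered pairs gave up to 22, and those that part 1 pair gave 0. In every other split the cell type difference partly cancels in the mean and adds to the spread, so low counts there are built in. The fit also took dye-swapped arrays of the same RNA as independent. No conclusion is drawn from these counts.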

How the results depend on the processing

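The alternatives with negative-control background, deposited net intensities, probes near the scanner limit left out, the reread value table and the block with a dye term were chosen after seeing the data. Of 116 named genes, 110 kept their direction under every alternative in which they were tested, and not all passed each filter. Counts of probes and genes past the threshold stayed within 1.5 times of 3553 and 1773 under other background corrections, normalizations and filters. With the replicate number as a block they were 4941 and 2539, with a dye term added 4831 and 2469. The block without the dye term ended no call and added 3 among named genes and 2 among lists, but its estimated correlation was -0.00258 (0.66 with the dye term), so it treated the 6 arrays as independent and gave the counts of a fit with no block. With the dye term the same 3 genes, KRT8, CYP19A1 and FSHR, and 1 list, ribosomal proteins (adjusted p = 0.0442), were added. The correlation was common to all probes, so calls of genes that vary widely between replicates may rest on too small an error. A block for slide or scan was not run. Aquantile leaves ratios unmoved by construction. Adjusted p alone gave 6051 probes and 2816 genes, treat 831 and 407, and a threshold of 0.01 gave 1093 and 514, as their construction sets. The value table gave 6443 and 2991 with no ratio required, and 0 and 0 (unadjusted p under 0.05: 3219 and 1323) with granulosa array 2 read like the other 2. Leaving out a replicate or an array gave 0 to 5009 probes and 0 to 2543 genes. The dye effect, 5883 probes, came to 0 without each replicate in turn, where 9602, 7231 and 7739 had an unadjusted p under 0.05, against 11445 in all. Of 12 lists called, 6 remained where both cell types had to be above background on all arrays, and 0 with an estimated correlation, which had little power.

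Directions turned as follows, and the cause was not tested except where given. The leave-out ranges also hold fits that kept the direction: primitive endoderm and STAR turned without replicate 2 alone, steroidogenesis kept it without replicate 3 or either of its arrays, and reference genes turned without each granulosa array. For lists the direction is that of the test, camera setting a list against other genes, so a median of either sign can go with it. Steroidogenesis genes, which pointed up, pointed down with no background correction (median -0.0559), no filter (-0.0891), the value table (-0.0110), that table reread (-0.0182), negative-control background (-0.0889), net intensities (-0.0583) and fry (-0.0636), and had medians of -0.21 to -0.0155 in the leave-outs. Ribosomal genes had 0.0602 with median centring and -0.13 with no normalization, oocyte genes -0.0899 with both cell types above background, and primitive endoderm -0.11 to -0.0188 in the leave-outs. Reference genes had -0.000747 with the table reread, -0.0341 without probes near the limit, 0.14 with fry and -0.0336 to 0.19 in the leave-outs. With no normalization CDH1 gave -0.0768 and GATA3 -0.0237. STAR gave 0.0797 with the table reread and -2.54 to 0.77 in the leave-outs. Without probes near the limit, another probe stood for CYB5A (0.61), RPL15 (0.0280) and SLC38A2 (0.0861). Signal over background limits the dim genes: 64.0% to 77.0% of probes lay above it in blastocysts and 58.2% to 78.3% in granulosa cells. For both, the higher shares were in Cy3 and the lower in Cy5.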

Other observations

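All tests in this part were chosen after the result was seen. The 3 granulosa RNA pools differed from each other far more than the 3 blastocyst pools. COL1A2, a fibrillar collagen, had log2 intensities of 13.46, 14.33 and 7.57 in the granulosa RNA of replicates 1 to 3, the endothelial receptor KDR 12.16, 11.85 and 6.82, and the leukocyte surface gene CD53 13.72, 11.33 and 9.07. CYP19A1, the aromatase, ran the other way at 10.41, 8.72 and 13.11, with FST at 12.12, 11.18 and 13.74 and INHBB at 10.70, 9.84 and 12.61. STAR stood at 11.78, 13.65 and 7.64. In an F test over the replicates on 6 arrays with a dye term, 13158 of 35034 probes passed limma's adjusted p of 0.05 and 4186 of these spanned a log2 ratio of at least 1. The granulosa channel had the wider range in 3490 of the 4186 (83.4%). This test sets the pools against the spread between dye-swapped arrays of the same RNA, so it compares these pools and not conditions.

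The fixed lists differed in the pool where their members were brightest, and no test of that grouping was run. The limits for these counts were an adjusted p under 0.05 in the F test on the ratio and a granulosa-channel log2 range of at least 1. The granulosa channel was not tested by itself. Of 21 blood and immune genes past both limits 20 were brightest in pool 1, of 12 theca and stroma genes 10 in pool 2, of 26 cell cycle genes 23 in pool 3, and of 15 steroidogenesis genes 12 in pool 3. All 8 oxidative phosphorylation genes and 6 of 8 granulosa genes were brightest in pool 3, and 13 of 17 basal lamina and matrix genes and 5 of 6 imprinted genes in pool 2. Of 20 ovulatory genes 9, 9 and 2 were brightest in pools 1 to 3, and of 8 immediate early genes 4, 4 and 0, so few or none in pool 3. Over all tested members, medians in pools 1 and 2 lay 0.76 and 0.75 above pool 3 for ovulatory genes. For immediate early genes they lay 0.53 and 0.32 above it. Other lists were divided: of 15 TGF-beta, BMP and WNT genes 4, 8 and 3 were brightest in pools 1 to 3, and of 8 oxidative stress genes 4, 0 and 4. Among genes with a blastocyst range under 1, the 4 widest granulosa ranges, chosen after their values were seen, belonged to CLCA1 (7.03, 15.22 and 7.09), PCK1 (7.31, 14.73 and 7.38), EPCAM (9.52, 14.54 and 7.33) and TFF3 (7.68, 14.49 and 7.60), all brightest in pool 2. IGF2, whose blastocyst range was wider, had 15.26, 15.28 and 7.56. Of 13 epithelial genes past both limits, 11 were brightest in pool 2.

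A dye or single-array artefact is argued against, since deviations of same-numbered arrays of opposite dye correlated at 0.845 or more across probes. For a lower share of granulosa cells as the whole cause of the differences among granulosa genes in replicate 2, the test is limited. Over 18 members of that list the difference between replicates 2 and 3 spanned 4.92, from -4.39 for CYP19A1 to 0.53 for CDH2. FST, at -2.56, and INHBB, at -2.77, lay between. Members near the floor in replicate 3, such as IGF1 (7.32) and KITLG (7.15), cannot fall further, so the span by itself cannot decide. Members bright in replicate 3 also fell unequally, with CYP19A1 (13.11 there) at -4.39 and GATA4 (14.36) at -0.52. A lower share alone would not give this in genes of granulosa cells only. A gene that other cells also express, as CDH2 may be, would fall less. GATA4 was bright in the blastocyst RNA too (12.80, 11.98 and 11.84 in replicates 1 to 3), so it is not a gene of granulosa cells only. The question therefore stays open. RNA of stromal, endothelial and blood cells in the pool of replicate 1 remains a hypothesis that the values allow. Over 60 members of those 3 lists the median difference from replicate 3 was 1.21, with 55 members higher, against -0.15 to 0.18 in 10000 random lists of like intensity. Random lists draw genes one by one, so genes that move together can fall outside that range, as cell cycle genes did with a median of -0.85. The range cannot tell RNA of other cells from another shared difference between pools. For replicate 2 the median over the same 60 members was 0.66, with 53 higher, against -0.16 to 0.15 in random lists. That size lay between the bounds set for the test after the values were seen, and the explanation stays open. By list, medians for replicates 1 and 2 were 0.87 and 1.11 for theca and stroma, 1.82 and 0.63 for blood and immune cells, and 0.42 and 0.54 for endothelium. Of the 60 members, 37 were above background in replicate 3 too and 1 is on another list. The most abundant were high, with COL3A1 at 15.14, 15.19 and 10.41 and BOLA-DRB3 at 15.01, 13.27 and 9.94. The granulosa cells were picked under a microscope and washed, which would remove some such cells. A difference in follicle stage between the pools also stays open and was not tested.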
